A study of Mus musculus with 6 samples.

How the data were processed

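RNA was sequenced from vascular smooth muscle cells of the mouse thoracic aorta in 6 libraries, 3 from wild type and 3 from Cmklr1 knockout animals. The authors deposited 1 table of raw read counts per gene, which per the labels rests on paired-end NovaSeq reads cleaned of adapters and low-quality reads; no scaling was applied to the deposited counts. The submitters' processing notes name the mouse build mm10 and DESeq 1.16.1. The aligner, the counting program and its strand setting are not given in the sources used here. The series text gives the study's rule for a changed gene as an unadjusted p under 0.05 with an absolute log2 fold change above 2.

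The table held 31324 features. The 24 features named by a bare number name no gene; they held 0.151% to 0.167% of the counts and were left out. Of the named features, 29866 (95.4%) matched 1 gene of the GRCm38 annotation, from which positions were taken. Among counts of 1 to 20, 68.9% to 75.2% were even, against 50.2% to 52.5% above 500, the pattern left when the mates of a read pair are counted separately; a run with counts halved was added for that reason. Mitochondrially encoded genes took 1.69% to 1.98% of the counts, and the 10 most abundant genes 4.4% to 5.2%. Libraries were compared by chi-square over genes with a summed count of at least 40: replicates 1 and 2 differed by 47.8 per gene in the wild type and 28.8 in the knockout, well above sampling noise, and all were kept as separate libraries.

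Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM factors, filterByExpr by genotype (18113 genes tested), glmQLFit without the robust option, glmQLFTest, and Benjamini-Hochberg adjustment with a threshold of 0.05. All tests were two-sided. An exact permutation of 3 against 3 libraries cannot give a p below 0.1. Each SE of an edgeR log2 fold change was computed as its absolute value over the square root of the quasi-likelihood F. It was not estimated directly, and it can understate the counting error of genes near 0 counts in a group. The 37 gene lists, the rule for named genes, the tests and the first set of other settings were fixed before the data were examined. Lists with at least 3 tested members (34) were tested by camera in limma 3.58.1 on log2 CPM with a prior count of 2, a trend and a preset correlation of 0.01. For named genes the rule required an adjusted p under 0.05, an absolute log2 fold change of at least 1, a mean log2 CPM of at least 1 and no overlap between the groups. It took the 7 largest changes and the 5 smallest p per direction; where no gene passed, as over all 6 libraries, it took the 5 per direction with the smallest unadjusted p, as values. From each list it took up to 4 called members with the largest change, or else the 2 most abundant; Cmklr1 was always named.

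Other settings fixed beforehand were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, no count filter, a filter of 1 CPM in 3 libraries, the robust fit, glmTreat, a replicate block, leaving out each library, camera with an estimated correlation, and fry. Chosen after seeing the data were the comparison of replicates 1 and 2 alone with its own alternatives, the interaction of genotype with replicate 3, replicate 3 as a batch term, counts halved, and the removal of chromosome medians. Where a group was left with 1 library, the spread was pooled and the lone library assumed to vary like the others. Replicate numbers come from the labels. After removal of genotype means, log2 CPM of libraries with the same number correlated at 0.14, 0.14 and 0.18 across genes. Each value was over the 0.1 set for treating numbers as pairs. The main fit nonetheless held genotype alone and was not paired, and the replicate block was run as an alternative. Wild type replicate 2 with knockout replicate 1 correlated at 0.17 and wild type 1 with knockout 2 at 0.09, and either with replicate 3 of the other genotype at -0.13 to -0.18, so the values set replicate 3 apart and do not tell 1 from 2.

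The test was tried on simulated data with 50 genes changed at each fold. Each gene was drawn independently, so the simulated libraries lacked the shared structure of the real ones. With the spread of 3 against 3 libraries it recovered 2%, 48%, 86% and 96% of genes changed 2-, 4-, 8- and 16-fold, with 12 false calls among 17865 unchanged genes (112 with DESeq2). At the spread of replicates 1 and 2 it recovered 92% at 2-fold and 100% above, with 17 false calls (26 with DESeq2). A fold against a pair of libraries at 0 was computed against a floor of 3 counts over the pair; such floors cover counting error only, and 3 read pairs are 6 counts if mates were counted separately. Chromosome medians used autosomal genes with a mean of at least 5 CPM and 1000 shuffles of genes among chromosomes. Summaries and figures were made in python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Pathway enrichment, transcription factor and protein interaction analyses named in the series text were not analysed here.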

Results

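Gene expression was measured by RNA sequencing in vascular smooth muscle cells from the thoracic aorta of mice, in 3 libraries from wild type animals and 3 from animals lacking Cmklr1. Cmklr1 encodes a G protein-coupled receptor for chemerin, a protein secreted by fat tissue and liver. The comparison asks which genes differ between the 2 genotypes in cells labelled as arterial smooth muscle. Some smooth muscle markers were low in wild type replicates 1 and 2, as given below, so the cell identity is taken from the labels. Total counts were 44571274, 56881201 and 53318587 in wild type replicates 1, 2 and 3, and 52894793, 55515756 and 48488015 in knockout replicates 1, 2 and 3. Between 22838 and 23844 features had a count in a library. Values below are CPM, read counts scaled to a common library size with TMM factors. The labels do not say whether the replicates of a genotype came from separate animals or cultures, so the p-values measure only the spread between these libraries, which may be technical.

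Cmklr1 itself was lower in all 3 knockout libraries than in all 3 wild type libraries. The gene lies on the minus strand of chromosome 5, from 113612354 to 113650426 in the GRCm38 build. Its raw counts were 868, 530 and 500 in wild type replicates 1 to 3, and 37, 24 and 43 in knockout replicates 1 to 3. In normalized terms the wild type mean was 12.9 ± 5.95 CPM (SD, n = 3) and the knockout mean 0.668 ± 0.219 CPM (SD, n = 3), which is 5.2% of the wild type level. The log2 fold change was -4.26 ± 0.48 (SE). In edgeR's quasi-likelihood test this difference had an adjusted p of 0.269, while DESeq2 gave an adjusted p of 4.85e-15. The call in edgeR turned on replicate 3: its adjusted p was 0.0275 without wild type replicate 3 and 0.0111 without knockout replicate 3. In replicates 1 and 2 alone it was 8.84e-06 in edgeR, and under the other settings tried it lay between 0.111 and 0.784. The labels do not state which part of the gene was removed, and counts per gene do not show where the remaining reads lay.

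The libraries did not group by genotype alone. Replicates 1 and 2 of the wild type resembled each other closely (r = 0.986 across tested genes on log2 CPM), as did replicates 1 and 2 of the knockout (r = 0.991). Replicate 3 of the wild type was closest to replicate 3 of the knockout (r = 0.976), and its correlation with wild type replicate 1 was 0.925. Between wild type replicate 1 and knockout replicate 1 the correlation was 0.881. These values run across genes, which are not independent replicates. Principal component 1, with 56.4% of the variance, ran from wild type replicates 1 and 2 to knockout replicates 1 and 2, and placed both replicate 3 libraries between them. Principal component 2, with 32% of the variance, set the replicate 3 libraries apart from the other 4.

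**Figure D1:**
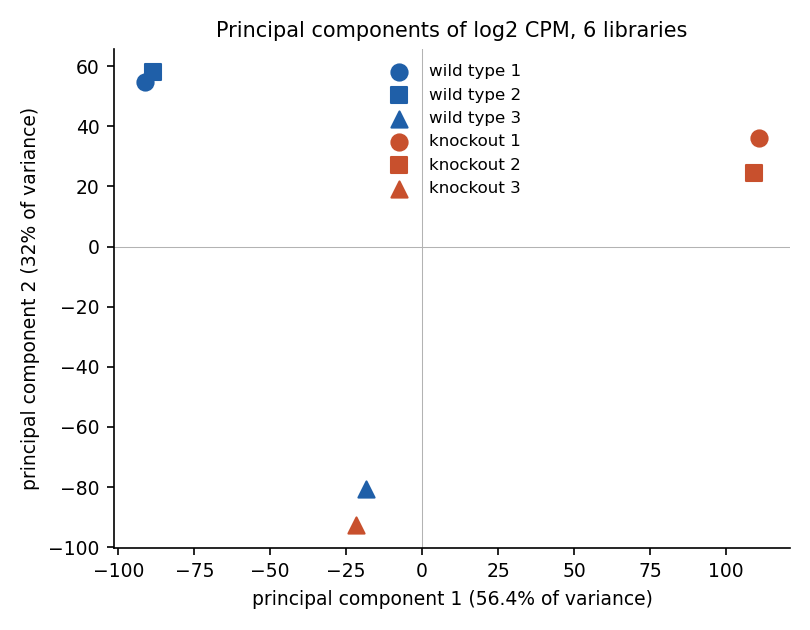
Each point is 1 library, placed by its scores on the first and second principal components of log2 CPM over 18113 tested genes; color marks genotype and shape marks the replicate number. Both replicate 3 libraries lie together, with scores of -18.5 and -21.7 on component 1, between the wild type pair near -91.2 and the knockout pair near 111.

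The 5 genes per direction with the smallest unadjusted p over all 6 libraries included genes of the matrix, of calcium binding and of G protein signalling. Islr, a secreted leucine-rich repeat protein of mesenchymal cells, stood at 27.0 ± 5.25 CPM in the wild type and 3.78 ± 0.779 CPM in the knockout (SD, n = 3 each). Col14a1, a collagen that associates with fibrils, stood at 406 ± 125 CPM in the wild type and 65.5 ± 15.3 CPM in the knockout. Kazald1, a secreted Kazal-domain protein, had means of 43.6 ± 10.1 and 7.43 ± 1.59 CPM, and Anxa4, a calcium-dependent phospholipid-binding annexin, had means of 212 ± 19.9 and 81.3 ± 4.88 CPM. In the other direction, the Wnt antagonist Dkk2 stood at 0.325 ± 0.101 CPM in the wild type and 4.94 ± 2.43 CPM in the knockout. The metallothionein Mt2 had 13.4 ± 3.75 and 93.9 ± 42.9 CPM; an overlapping annotated feature had almost the same counts, so the split of reads between them is uncertain. Gnai1, an inhibitory G protein subunit, had 13.9 ± 2.51 and 49.97 ± 16.5 CPM. Rgs11, a regulator of G protein signalling, had 1.36 ± 0.539 and 13.8 ± 7.0 CPM, and Fign, a microtubule-severing ATPase, had 0.501 ± 0.143 and 3.47 ± 1.31 CPM. Each of these genes had 3 knockout values on 1 side of all 3 wild type values. That held for 3400 of 18113 genes (18.8%). A share of 10% would be the average for 6 exchangeable libraries. These libraries resembled each other in groups, so 10% is no measure of chance here and the excess does not show an effect of genotype. The named genes were picked by smallest p, which favors no overlap.

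None of these genes passed the adjusted threshold over all 6 libraries, because none of 18113 did. edgeR's quasi-likelihood test called 0 genes, and its smallest adjusted p was 0.269. At an unadjusted p under 0.05 it held 2675 genes, limma-voom called 0 after adjustment, and DESeq2 called 1056 (529 higher and 527 lower in the knockout). DESeq2 was run without the count filter, on 29701 features, and 921 of its calls lay among the 18113 genes. All 10 named genes were among the DESeq2 calls, with adjusted p from 4.85e-15 to 0.000122. The rule stated for the study, an unadjusted p under 0.05 with an absolute log2 fold change above 2, gave 723 genes, 418 higher and 305 lower. The excess of higher genes depended on the fit, as limma-voom gave 353 higher and 371 lower, the replicate block 227 and 285, and leaving out knockout replicate 1 left 265 and 306. Leaving out wild type replicate 3 brought the edgeR calls from 0 to 751, and leaving out knockout replicate 3 brought them to 2259. In simulated data with the spread of these 6 libraries, the test recovered 48% of 4-fold and 86% of 8-fold changes. The simulated genes varied independently, without the structure that replicate 3 gave the real libraries, so these rates do not carry over to them. Cmklr1, with a log2 fold change of -4.26, was itself not called by edgeR over all 6 libraries.

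**Figure D2:**
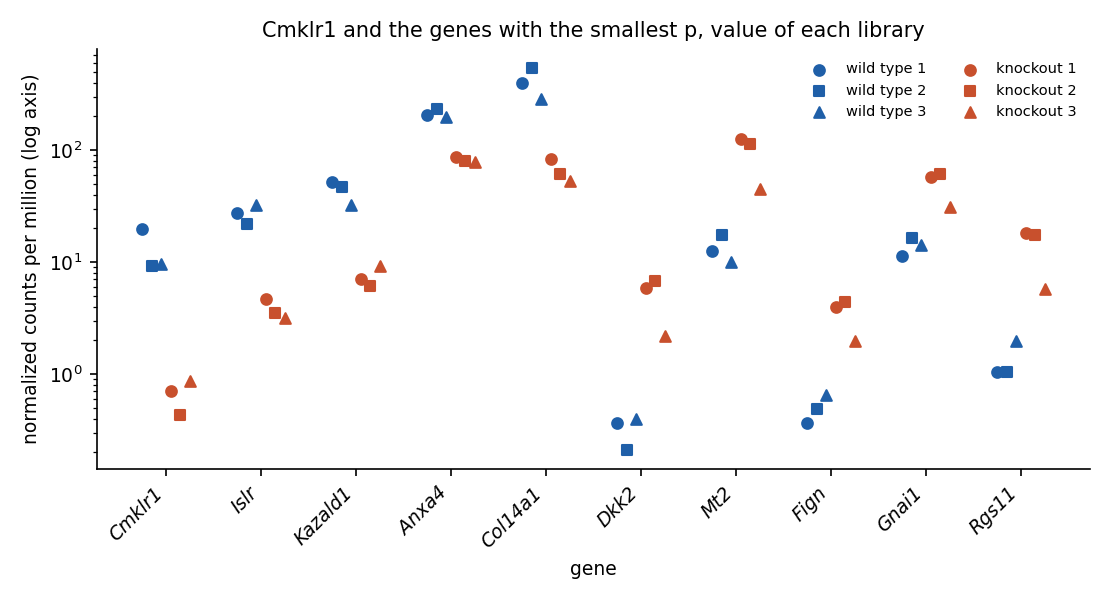
Normalized counts (CPM), on a log axis, of Cmklr1 and the other 9 genes with the smallest unadjusted p per direction, with 1 point per library (blue, wild type; red, knockout; shape, replicate number). In every gene shown, the 3 knockout values lie on 1 side of the 3 wild type values; for Anxa4 the wild type values run from 196 to 234 and the knockout values from 77.5 to 86.8.

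Over all 6 libraries, 6 of 34 fixed gene lists moved in limma's camera test, in each case beside 0 members called by edgeR over all genes. The interferon response list rose (46 genes, median log2 fold change 2.89, adjusted p = 6.55e-08) and the cell cycle list fell (48 genes, median -0.53, adjusted p = 1.64e-08). Notch pathway genes fell (median -0.80, adjusted p = 0.00446), with 4 of 15 members lower and 1 higher when adjusted over the list alone. Osteochondrogenic genes fell (median -0.52, adjusted p = 0.0171; 1 of 19 lower and 1 higher adjusted over the list alone), and so did oxidant production and antioxidant defence (median -0.33, adjusted p = 0.0212; 1 of 34 lower). Cholesterol synthesis and uptake rose (30 genes, median 0.37, adjusted p = 0.0421); in camera with the replicate block the adjusted p was 0.104. In the replicate 3 pair alone the interferon median was 0.12 (26 of 46 genes higher in the knockout library). The cell cycle median lay the other way at 0.31 (41 of 48 higher), and so did the cholesterol median at -0.48 (25 of 30 lower). The Notch, osteochondrogenic and oxidant medians were -0.22, -0.15 and 0.06. With an estimated correlation between genes, camera gave adjusted p = 0.813 for each of the 6 lists. The osteochondrogenic call ended without wild type replicate 3 (camera adjusted p = 0.0995) or knockout replicate 1 (0.197), the oxidant call without wild type replicate 2 (0.0766). The Notch median went to -0.51 without wild type replicate 2, -1.25 without wild type replicate 3 and -1.68 without knockout replicate 3. Without knockout replicate 3 the cell cycle median was -0.99 and the osteochondrogenic median -0.88, and without wild type replicate 2 the oxidant median was -0.18. The cholesterol median was 0.24 without wild type replicate 1, 0.22 without knockout replicate 2, 0.65 without wild type replicate 3 and 0.64 without knockout replicate 3. Of the cholesterol call, the camera adjusted p ran from 0.0917 to 0.276 without wild type replicate 1, wild type replicate 2, knockout replicate 1 or knockout replicate 2 in turn.

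Because replicate 3 stood apart in both genotypes, replicates 1 and 2 were also compared alone, 2 knockout against 2 wild type libraries, and set beside the single replicate 3 pair; this comparison was chosen after the data had been examined. In replicates 1 and 2, edgeR called 9002 of 18113 genes at an adjusted p under 0.05, 4513 higher and 4489 lower in the knockout. The spread between libraries of a genotype, as the biological coefficient of variation of the fit, was 13.4% there and 46.6% over all 6 libraries. Of the 9002 genes, 3886 (43.2%) had the same sign in replicate 3. Across genes, the log2 ratios of the 2 parts had a correlation of -0.00916. A test of the difference between the 2 parts, the interaction of genotype with replicate 3, passed the threshold for 6268 genes in edgeR, under the assumption that each single replicate 3 library varies like the others. Replicates 1 and 2 of a genotype were nearly alike, so these p-values measure a narrow spread. Whether each pair came from 1 culture is not given in the sources used here. Across genotypes the replicate 3 libraries were the better matched, at r = 0.976 against 0.881 between the replicate 1 libraries, but they are 1 library per genotype. The wild type and knockout pairs of replicates 1 and 2 also differed in cell type markers, in Xist and in chromosome medians, as given below. A change through the receptor therefore cannot be told apart from another difference between the pairs. In replicates 1 and 2, rose and fell mean higher and lower in the knockout pair, whatever the cause. Called genes with over 2-fold differences shared their direction with over 2-fold ratios in replicate 3 more often than independent lists would (184 higher in both where 105.9 are expected, 262 lower in both where 140.6 are expected). Opposite directions exceeded chance too, with 302 genes higher and then lower (157.2 expected) and 158 lower and then higher (94.8 expected).

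The genes that differed most in replicates 1 and 2 separated the 2 pairs almost as present against absent. Lrrn4, a mesothelial membrane protein, had 0 counts in wild type replicates 1 and 2 and 585 and 577 CPM in knockout replicates 1 and 2, at least 19600-fold higher against a floor of 3 counts over the wild type pair. The maternally expressed noncoding RNA Rian was at least 9030-fold higher and the adhesion protein Adam23 at least 4920-fold higher on the same floor. If the mates of each read pair were counted separately, as the share of even low counts hints, 3 pairs are 6 counts, and these bounds become 9780-, 4520- and 2460-fold. Meg3, a noncoding RNA of the same imprinted region as Rian, had 423 and 352 CPM in knockout replicates 1 and 2 against 0.0909 and 0.0351 in the wild type pair. The matrix proteins Thbs2 (log2 fold change 13.25 ± 0.24 SE) and Hmcn1 (13.11 ± 0.24) rose as well. In the wild type pair Thbs2 lay at 0.0909 and 0.0702 CPM and Hmcn1 at 0.136 and 0.0702 CPM. With so few counts these folds are less certain than the SE reads. The surface glycoprotein Thy1 rose too, at 491 and 504 CPM against 2 counts in the wild type pair. By smallest p, the neuropeptide receptor Adcyap1r1 (10.17 ± 0.19), Xist (11.74 ± 0.22), Plac8 (8.43 ± 0.17), the epithelial transcription factor Bnc1 (9.47 ± 0.20) and the phosphatase subunit Ppp2r2b (8.53 ± 0.18) rose. Each had an adjusted p of 2.02e-08 or below in edgeR.

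Among the genes that fell most in replicates 1 and 2, the carboxylesterase Ces1g was at least 5090-fold lower, with 0 counts in the knockout pair (2550-fold on a floor of 6 counts). The aldehyde dehydrogenase Aldh3a1 stood at 1959 and 2603 CPM in the wild type pair and 2.38 and 1.15 CPM in the knockout pair. The water channel Aqp1 (log2 fold change -9.21 ± 0.35 SE), the membrane proteolipid Mal (-8.38 ± 0.21) and the secreted Slurp1 (-8.39 ± 0.31) fell, as did Sprr2a1, Sprr2a2 and Sprr2a3 (-8.73, -8.79 and -8.90), near-identical cornified envelope genes whose shares of the reads are uncertain. Ephb6 (-5.73 ± 0.14), Nrarp (-7.30 ± 0.22), the neurotrophin receptor Ntrk3 (-7.09 ± 0.22) and the ligand Wnt4 (-7.48 ± 0.24) fell too, all with an adjusted p of 2.71e-07 or below in edgeR. In the replicate 3 pair the log2 ratios of these genes were smaller. Of the 12 named as higher, 9 were lower in the knockout library of replicate 3, down to -2.25 for Lrrn4. Thbs2 stood at 19.7 CPM in the wild type and 15.7 CPM in the knockout library, and Plac8 at 269 and 309 CPM. Of the 12 named as lower, 11 were lower there too. Their log2 ratios included -3.66, -3.46 and -3.40 for Sprr2a1, Sprr2a2 and Sprr2a3 (Sprr2a1 108 and 8.5 CPM), -1.82 for Slurp1 and -1.76 for Wnt4.

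**Figure D3:**
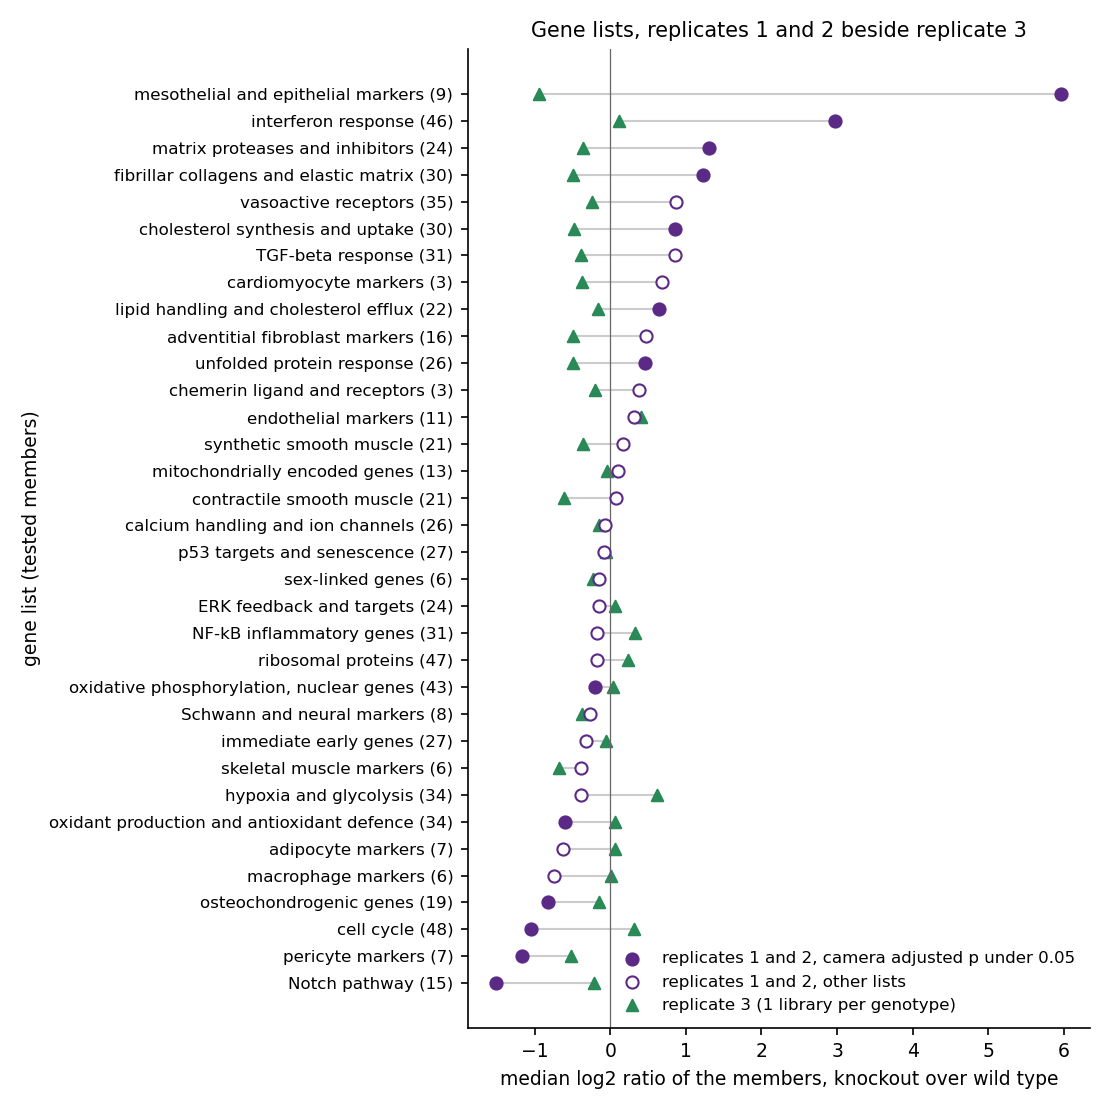
Median log2 ratio of knockout over wild type for the tested members of each of 34 gene lists, in replicates 1 and 2 (circles; filled where camera's adjusted p is under 0.05) and in the single replicate 3 pair (triangles). The interferon list has a median of 2.98 in replicates 1 and 2 and 0.12 in replicate 3; the mesothelial and epithelial median of 5.97 takes genes with 0 counts in a pair at their bound.

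Interferon-stimulated genes were higher as a group in knockout replicates 1 and 2. Of 46 tested members 41 rose and 0 fell (42 and 0 adjusted over the list alone), with a median log2 fold change of 2.98 and camera's adjusted p = 9.95e-21; with an estimated correlation the adjusted p was 0.53. The ubiquitin-like Isg15 stood at 0.489 CPM on average in the wild type pair and at 50.4 and 59.7 CPM in the knockout pair. Iigp1 (log2 fold change 7.31 ± 0.27 SE), Ifi44 (6.63 ± 0.26) and Oasl2 (6.55 ± 0.15) rose likewise. In replicate 3 these 4 genes lay under 1.2 CPM in both genotypes, and the list median was 0.12. The interaction passed for 36 of the 46 genes. NF-kB inflammatory genes went both ways, with 9 of 31 higher and 11 lower (9 and 11 adjusted over the list alone; camera adjusted p = 0.669). Among them the adhesion molecule Icam1 rose from 1.73 and 1.98 CPM to 96.2 and 90.03 CPM, the chemokine Cxcl1 fell (-4.32 ± 0.20), Lcn2 fell (-8.35 ± 0.46) and Cxcl10 rose (2.98 ± 0.50). The NF-kB list had camera's adjusted p = 0.805 over all 6 libraries, and its most abundant members Cxcl12 and Vcam1 had DESeq2 adjusted p of 0.936 and 0.603.

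Cell cycle genes were lower as a group in knockout replicates 1 and 2: 45 of 48 fell and 0 rose (45 and 0 adjusted over the list alone), with a median log2 fold change of -1.05 and camera's adjusted p = 8.27e-16; the adjusted p was 0.53 with an estimated correlation. The cyclin Ccnd1 fell from 3506 and 2711 CPM to 640 and 597 CPM. Replication genes Mcm5 (-2.37 ± 0.14 SE) and Cdc6 (-2.16 ± 0.14) fell, and so did Uhrf1 (-1.86 ± 0.14), which maintains DNA methylation. In replicate 3 the list lay the other way, with a median of 0.31 and 41 of 48 genes higher in the knockout library, and the interaction passed for 45 genes, each upward. Notch pathway genes fell as well (10 of 15 lower and 3 higher; 12 and 3 adjusted over the list alone; median -1.51, camera adjusted p = 0.00637, and 0.53 with an estimated correlation), led by the Notch target Nrarp, the ligands Jag1 (-2.77 ± 0.14) and Jag2 (-2.76 ± 0.30), and the receptor Notch1 (-2.46 ± 0.15). ERK feedback genes split, with 8 of 24 higher and 9 lower (8 and 10 adjusted over the list alone; camera adjusted p = 0.674). Spry1 and Spry4, inhibitors of receptor tyrosine kinase signalling, rose (2.76 ± 0.27 and 2.71 ± 0.22), while the transcription factor Etv4 (-2.72 ± 0.28) and the phosphatase Dusp1 (-2.52 ± 0.14) fell. Of 27 immediate early genes 9 rose and 12 fell (10 and 14 adjusted over the list alone; camera adjusted p = 0.531), among them Fos (2.54 ± 0.23), Klf2 (2.24 ± 0.39) and Egr1 (1.92 ± 0.26) upward. Among 27 p53 targets and senescence genes 7 rose and 11 fell (8 and 11 adjusted over the list alone; camera adjusted p = 0.729): the cell cycle inhibitor Cdkn2a rose from 11.8 and 8.45 CPM to 81.1 and 85.0 CPM, and Perp (-4.27 ± 0.14), Gdf15 (-1.71 ± 0.20) and Pmaip1 (-1.37 ± 0.16) fell. With replicate 3 included, camera's adjusted p was 0.963 for ERK feedback, 0.7 for immediate early and 0.975 for p53 genes.

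Matrix genes rose in knockout replicates 1 and 2. Among fibrillar collagens and elastic matrix genes 22 of 30 rose and 5 fell (22 and 5 adjusted over the list alone; median 1.23, camera adjusted p = 0.000101, and 0.53 with an estimated correlation). Col3a1 rose from 60.6 and 122 CPM to 1529 and 2140 CPM, and Fmod (4.89 ± 0.40 SE), the crosslinking enzyme Loxl1 (3.79 ± 0.13) and Col6a2 (3.74 ± 0.14) rose with it, whereas Col1a1, at 3356 to 4827 CPM outside the knockout pair, fell (-0.66 ± 0.13). In replicate 3, 26 of the 30 genes were lower in the knockout library (median -0.49), and the interaction passed for 21 genes, each downward. Matrix proteases and inhibitors followed, with 16 of 24 higher and 6 lower (17 and 6 adjusted over the list alone; median 1.30, camera adjusted p = 0.00392, and 0.53 with an estimated correlation). The collagenolytic cathepsin Ctsk (8.13 ± 0.37), Mmp23 (4.60 ± 0.19) and Adamts15 (4.01 ± 0.36) rose and the gelatinase Mmp2 fell (-4.34 ± 0.15). For TGF-beta response genes the count was 18 of 31 higher and 9 lower (18 and 9 adjusted over the list alone), with camera's adjusted p = 0.0815; Ltbp2 (7.52 ± 0.46), Tgfbi (6.90 ± 0.29), Cyr61 (2.85 ± 0.14) and Tgfbr3 (2.72 ± 0.18) rose. Osteochondrogenic genes fell as a list (9 of 19 lower and 3 higher, the same numbers adjusted over the list alone; median -0.83, camera adjusted p = 0.0236, and 0.53 with an estimated correlation). The cartilage transcription factor Sox9 (-2.59 ± 0.13) and the pyrophosphate transporter Ank (-3.01 ± 0.13) fell, and Enpp1 (2.95 ± 0.27) and Tnfrsf11b (2.76 ± 0.19), which restrain mineralization and osteoclasts, rose. In replicate 3, 19 of the 24 protease and inhibitor genes (median -0.35) and 26 of the 31 TGF-beta genes (median -0.38) were lower in the knockout library, and the interaction passed downward for 16 and 18 genes of the lists and upward for 4 and 6. Of the osteochondrogenic genes, 13 of 19 were lower there. In the fit of all 6 libraries, camera's adjusted p was 0.0695 for collagens, 0.0695 for proteases and 0.852 for the TGF-beta list.

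Contractile smooth muscle genes went both ways in replicates 1 and 2, where 9 of 21 rose and 6 fell (9 and 6 adjusted over the list alone; camera adjusted p = 0.374). Tagln, an actin-binding marker of differentiated smooth muscle, stood at 2.5 and 4.04 CPM in wild type replicates 1 and 2, 140 CPM in wild type replicate 3, 155 and 188 CPM in knockout replicates 1 and 2, and 58.2 CPM in knockout replicate 3. Myl9 (6.13 ± 0.26 SE), the myosin kinase Mylk (2.99 ± 0.28) and Mrvi1 (2.56 ± 0.25) rose in replicates 1 and 2. Myl9 lay at 0.227 and 0.281 CPM in wild type replicates 1 and 2, while the list member Tpm1 stood at 585 and 596 CPM there. In replicate 3, 17 of the 21 genes were lower in the knockout library, with a median of -0.61. Camera on the interaction passed downward (adjusted p = 0.0214), with 10 genes passing downward and 3 upward in edgeR. Of 21 genes of the synthetic state 9 rose and 7 fell (9 and 8 adjusted over the list alone; camera adjusted p = 0.398). In replicate 3, 16 of the 21 were lower in the knockout library (median -0.35), and camera on the interaction passed downward (adjusted p = 0.0274). The growth factor receptor Pdgfra rose from 2.23 and 2.81 CPM to 237 and 239 CPM and Tnc from 11.6 and 8.85 CPM to 956 and 883 CPM; Col8a1 rose (3.33 ± 0.25) and Ly6a fell (-4.55 ± 0.33). Calcium handling genes split evenly, 9 of 26 higher and 9 lower (10 and 10 adjusted over the list alone; camera adjusted p = 0.735), with the chloride channel Ano1 (-4.67 ± 0.21), the potassium channel Kcnj2 (-3.67 ± 0.21) and the calcium pump Atp2b4 (-3.50 ± 0.32) lower and the channel subunit Cacna2d1 (2.65 ± 0.15) higher. Of 35 vasoactive receptors 18 rose and 12 fell (18 and 12 adjusted over the list alone; camera adjusted p = 0.218): Adora2b (5.07 ± 0.24) and Npr3 (2.92 ± 0.19) rose, and the adrenergic receptor Adra1b (-3.17 ± 0.22) and P2ry2 (-2.81 ± 0.18) fell. The chemerin list held 3 tested genes, of which Cmklr1 fell; the ligand gene Rarres2 lay between 1.05 and 2.4 CPM in all 6 libraries, and camera's adjusted p was 0.768. With replicate 3 included, camera's adjusted p was 0.975 for the contractile and for the synthetic list, 0.546 for calcium handling and for the chemerin list, and 0.739 for vasoactive receptors.

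Lists of lipid genes and of the unfolded protein response rose in knockout replicates 1 and 2. Among cholesterol synthesis and uptake genes 21 of 30 rose and 2 fell (22 and 2 adjusted over the list alone; median 0.86, camera adjusted p = 8.04e-05, and 0.53 with an estimated correlation), including the desaturase Scd2 (2.25 ± 0.14 SE), Lss (1.57 ± 0.14) and Sc5d (1.38 ± 0.15). In replicate 3, 25 of the 30 were lower in the knockout library, and the interaction passed downward for 21. Lipid handling genes rose with 13 of 22 higher and 3 lower (13 and 4 adjusted over the list alone; camera adjusted p = 0.0379, and 0.53 with an estimated correlation); the scavenger receptor Olr1 (5.03 ± 0.30), the nuclear receptor Pparg (3.29 ± 0.30) and Fabp5 (2.02 ± 0.23) rose, and the sterol-sensing nuclear receptor Nr1h3 fell (-3.26 ± 0.19). Genes of the unfolded protein response rose (16 of 26 higher and 3 lower, the same numbers adjusted over the list alone; camera adjusted p = 0.0145, and 0.721 with an estimated correlation), among them Ddit3 (0.94 ± 0.17), Atf6 (0.91 ± 0.13), Sesn2 (0.85 ± 0.13) and Dnajb9 (0.76 ± 0.20). In replicate 3 the unfolded protein response lay the other way, with 21 of 26 genes lower in the knockout library (median -0.49), and the interaction passed downward for 16 and upward for 1. Of the lipid handling genes, 13 of 22 were lower there. In the fit of all 6 libraries, camera's adjusted p was 0.256 for lipid handling and 0.7 for the unfolded protein response.

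Of 5 lists of energy, redox and translation genes, 2 fell in camera in knockout replicates 1 and 2. Neither fall was seen in replicate 3, where the oxidant median was 0.06 and the oxidative phosphorylation median 0.03. There 17 of 34 oxidant genes and 24 of 43 oxidative phosphorylation genes were higher in the knockout library. Oxidant and antioxidant genes fell with 19 of 34 lower and 4 higher (20 and 4 adjusted over the list alone; camera adjusted p = 0.00833, and 0.721 with an estimated correlation); the Nrf2 targets Nqo1 (-2.81 ± 0.12 SE), Slc7a11 (-2.64 ± 0.18) and Gclc (-2.32 ± 0.17) fell and the oxidase subunit Cyba rose (4.78 ± 0.15). Nuclear genes of oxidative phosphorylation fell (18 of 43 lower and 3 higher, the same numbers adjusted over the list alone; camera adjusted p = 0.0351, and 0.721 with an estimated correlation), with Cyc1 (-1.18 ± 0.11), Cox6c (-1.03 ± 0.15), Ndufb9 (-0.97 ± 0.11) and Ndufa1 (-0.82 ± 0.15) lower. Hypoxia and glycolysis genes had 16 of 34 lower and 4 higher (16 and 4 adjusted over the list alone; camera adjusted p = 0.14): Egln3 (-2.29 ± 0.19) and the hexokinase Hk1 (-1.60 ± 0.13) fell, and the peptide hormone gene Adm (6.20 ± 0.25) and the lactate transporter Slc16a1 (2.26 ± 0.15) rose. In replicate 3 the hypoxia list had 28 of 34 genes higher in the knockout library, with a median of 0.62, and the interaction passed upward for 20. Of 47 ribosomal protein genes 15 fell and 4 rose (14 and 4 adjusted over the list alone; camera adjusted p = 0.131), including Rps16 (-0.87) and Rpl30 (-0.80) among those that fell; all 47 were higher in the knockout library of replicate 3, by a median of 0.23. Of 13 mitochondrially encoded genes 4 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.921): mt-Nd6 (-0.79 ± 0.14) and mt-Co1 (-0.63 ± 0.13) fell and mt-Nd3 (0.68 ± 0.14) and mt-Atp6 (0.59 ± 0.20) rose; nuclear copies share reads with such genes, so single values are uncertain. With replicate 3 included, camera's adjusted p was 0.0695 for oxidative phosphorylation, 0.975 for hypoxia and for ribosomal proteins, and 0.981 for mitochondrial genes.

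Mesothelial and epithelial markers rose in knockout replicates 1 and 2 (6 of 9 higher and 2 lower, the same numbers adjusted over the list alone; camera adjusted p = 0.00836, and 0.721 with an estimated correlation): the transcription factor Wt1 stood at 65.1 and 58.2 CPM against 0.182 and 0.211 CPM, and Upk3b (7.72 ± 0.33 SE) and Msln (6.44 ± 0.33) rose with Lrrn4. In both replicate 3 libraries Wt1 lay under 0.2 CPM, and 7 of the 9 markers were lower in the knockout library there. Pericyte markers fell (6 of 7 lower and 1 higher, the same numbers adjusted over the list alone; camera adjusted p = 0.00821, and 0.721 with an estimated correlation), with Cspg4 going from 435 and 356 CPM to 11.8 and 13.3 CPM and Cox4i2 (-5.56 ± 0.22), Mcam (-3.11 ± 0.16) and Rgs5 (-1.17 ± 0.26) lower. Of the 7 pericyte markers, 5 were lower and 2 higher in the knockout library of replicate 3 (median -0.51, against -1.17 in replicates 1 and 2). Over all 6 libraries the pericyte list had camera's adjusted p = 0.0695, which became 0.0152 with the replicate block. The mesothelial list had camera's adjusted p = 0.0704 over these libraries, with 5 of 9 members higher adjusted over the list alone. Adventitial fibroblast markers split, 7 of 16 higher and 5 lower (7 and 5 adjusted over the list alone; camera adjusted p = 0.374): Serpinf1 (10.69 ± 0.24) and Pdgfra (6.56 ± 0.16) rose and Ly6c1 (-5.32 ± 0.29) and Ly6a fell. In replicate 3, 13 of the 16 were lower in the knockout library (median -0.49), and camera on the interaction passed downward (adjusted p = 0.0373).

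The remaining marker lists were sparse or divided. Of 11 endothelial markers 3 rose and 4 fell (camera adjusted p = 0.969); Eng stood at 116 and 115 CPM in wild type replicates 1 and 2, 228 and 232 CPM in knockout replicates 1 and 2, and 10.01 and 8.93 CPM in replicate 3 of the wild type and the knockout, while Ptprb rose (0.74 ± 0.26) and Flt1 fell (-1.18 ± 0.35), each under 6 CPM. Adipocyte markers had 2 of 7 higher and 3 lower (camera adjusted p = 0.42), with Plin4 (-4.67 ± 0.27) and Cebpa (-4.20 ± 0.24) lower and Fabp4 (1.73 ± 0.38) higher. Of 8 Schwann and neural markers 3 rose and 3 fell (camera adjusted p = 0.988), among them Mbp (5.10 ± 0.30), S100b (2.99 ± 0.33), Tubb3 (-2.82 ± 0.14) and Pmp22 (-0.46 ± 0.13). Macrophage markers had 2 of 6 lower and 0 higher (camera adjusted p = 0.171), with Cd14 (-0.77 ± 0.16) among them. Skeletal muscle markers had 1 of 6 higher and 1 lower (camera adjusted p = 0.921; Actn3 1.47 ± 0.41) and cardiomyocyte markers 1 of 3 higher and 1 lower (camera adjusted p = 0.971), where Tnnt2 fell (-3.18 ± 0.29). Adjusted over the list alone, the higher and lower counts were unchanged for endothelial, adipocyte, Schwann and macrophage markers, 1 and 0 for skeletal muscle, and 2 and 1 for cardiomyocyte markers. Lymphocyte markers had 2 tested members and erythroid markers 1, too few for the list test, and neutrophil markers had 0: Lck and Cd79a lay under 0.8 CPM and Alas2 under 0.65 CPM in every library. Over all 6 libraries camera's adjusted p was 0.975 for endothelial and for fibroblast markers, 0.546 for adipocyte, 0.856 for Schwann and for cardiomyocyte, 0.326 for macrophage and 0.852 for skeletal muscle markers. In replicates 1 and 2, the median, the mean and the camera direction differed in sign for the chemerin, immediate early, endothelial, Schwann, cardiomyocyte and sex-linked lists, none of them called; with all 6 libraries this held for the contractile, synthetic, chemerin, NF-kB, p53, endothelial, fibroblast, Schwann, cardiomyocyte and sex-linked lists, none called either.

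Sex-linked genes also separated the libraries. Xist, the X-inactivation transcript, stood at 0.0909 and 0.0702 CPM in wild type replicates 1 and 2, 263 and 294 CPM in knockout replicates 1 and 2, and 48.0 and 34.01 CPM in replicate 3 of the wild type and the knockout. The summed CPM of 4 Y-linked genes was 167, 181 and 310 in wild type replicates 1 to 3, and 151, 140 and 289 in knockout replicates 1 to 3. Of 6 sex-linked genes 2 rose and 2 fell in replicates 1 and 2 (the same numbers adjusted over the list alone; camera adjusted p = 0.623, and 0.803 over all 6 libraries); Kdm5d (-0.52 ± 0.13 SE) and Eif2s3y (-0.38 ± 0.11) were the ones that fell. Tsix overlaps Xist on the opposite strand, and whether reads were counted by strand is not given in the sources used here. Xist parted the wild type pair of replicates 1 and 2 from the knockout pair, while Y-linked genes were counted in all 6 libraries. A difference in sex makeup between these pairs cannot be told apart from genotype. The list mixes Xist with Y-linked genes, so its camera test does not measure such a difference.

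Shifts of whole chromosomes accompanied the differences between libraries. Among 11256 autosomal genes with a mean of at least 5 CPM, the median log2 difference of knockout from wild type in replicates 1 and 2 ran from -0.80 on chromosome 15 to 0.59 on chromosome 3. The SD of the 19 chromosome medians was 0.321, and the highest of 1000 shuffles of genes among chromosomes gave 0.0568 (p = 0.001 in this permutation test, the smallest it can give). Shifts within a genotype were large too. For replicate 3 minus replicates 1 and 2 the SD was 0.291 in the wild type (highest of the shuffles 0.0477) and 0.191 in the knockout (highest 0.0568). For replicate 2 minus replicate 1 it was 0.0237 in the wild type (highest of the shuffles 0.0179) and 0.0117 in the knockout (highest 0.0153), and for knockout minus wild type in replicate 3 it was 0.0417 (highest 0.0344). Small shifts thus also passed the shuffles, and the sizes set the contrasts apart. The chromosome profiles of the replicate 3 libraries of both genotypes resembled each other (r = 0.958 across 19 autosomes, against -0.613 between wild type replicates 1 and 3), as did those of replicates 1 and 2 of the wild type (r = 0.991) and of the knockout (r = 0.991).

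**Figure D4:**
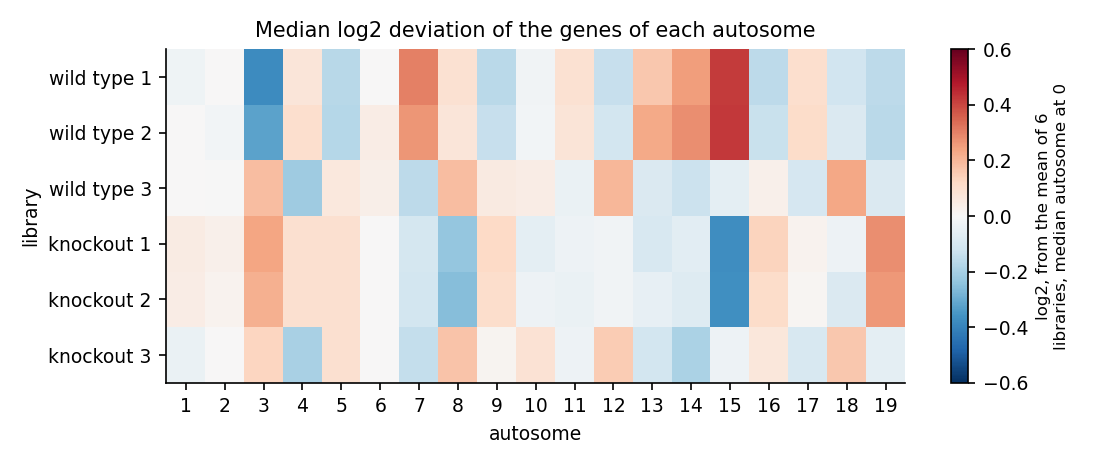
Color gives, for each library (rows) and autosome (columns), the median log2 deviation of its genes from their mean over the 6 libraries, with the median autosome of each library set to 0. Chromosome 15 lies at 0.42 and 0.425 in wild type replicates 1 and 2, at -0.373 and -0.369 in knockout replicates 1 and 2, and at -0.06 and -0.029 in the replicate 3 libraries.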

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

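The interaction test, the test of exchanged labels, the test of an additive shift, the test of genotype as the cause of chromosome shifts and the removal of chromosome medians were chosen only after the result was seen; the other tests in this part were fixed before their results.

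The difference of knockout from wild type was not the same in replicate 3 and in replicates 1 and 2. Cmklr1 was lower in both parts. For other genes the design cannot tell genotype from other differences between the libraries. The interaction of genotype with replicate 3 passed edgeR's adjusted threshold for 6268 of 18113 genes (34.6%), 3063 upward and 3205 downward, and camera on the interaction passed for 18 of 34 lists. Of the genes named over all 6 libraries, Rgs11 (log2 interaction -2.55, edgeR adjusted p = 0.000479), Dkk2 (-2.05, 0.0296), Fign (-1.68, 0.0487), Gnai1 (-0.97, 0.0292) and Mt2 (-0.82, 0.0420) were higher in the knockout in both parts, by less in replicate 3. Kazald1 was lower in both parts, by less in replicate 3 (log2 interaction 1.09, edgeR adjusted p = 0.00725). Anxa4 (0.06, 0.864), Col14a1 (0.26, 0.556), Islr (-0.76, 0.109) and Cmklr1 (1.21, 0.202) did not pass. The 24 genes named for replicates 1 and 2 passed, but they were picked for extreme values there, so this adds no support. Features named by a bare number, which entered no comparison, held up to 0.167% of a library's counts.

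Replicate 3 of the wild type resembled replicate 3 of the knockout more than its own genotype. An exchange of these 2 labels is argued against by Cmklr1, whose CPM in wild type replicate 3 was 11 times that in knockout replicate 3. A shift common to both replicate 3 libraries and additive on the log scale would leave the log2 ratios alike in the 2 parts. The log2 ratios of knockout over wild type correlated at -0.00916 across genes, which argues against such a shift as the only difference between the parts. A shared shift beside other differences stays open. Principal component 2 put the replicate 3 libraries at -80.7 (wild type) and -92.7 (knockout), and the other libraries at 24.3 to 58.1. Chromosome-wide shifts are argued against as the whole cause, since after their removal the edgeR dispersion was 0.209 against 0.217 before, with 0 genes called either way. A difference in culture, passage or cell makeup between replicate 3 and the rest may contribute and was not tested as a cause. The design names no biological difference between replicate numbers. Within replicates 1 and 2, 6 of 9 mesothelial and epithelial markers were higher in the knockout pair and 2 lower. Of 7 pericyte markers 6 were lower there and 1 higher. Cell makeup may thus differ between these pairs too, which the design does not separate from genotype.

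Whole chromosomes shifted together between libraries. GC content and transcript length are argued against: after a lowess fit on either, 98.0% of the SD of chromosome medians remained for knockout minus wild type in replicates 1 and 2. Genotype is argued against as the whole cause, since chromosomes shifted within a genotype: for replicate 3 minus replicates 1 and 2 the SD of the medians was 0.291 in the wild type and 0.191 in the knockout, against 0.0237 and 0.0117 for replicate 2 minus replicate 1. The highest of 1000 shuffles gave 0.0477 and 0.0568 for the former. A difference in chromosome number between cultures may underlie the shifts and stays open: the proximal and distal parts of autosomes, divided at the middle gene, shifted with r = 0.777 for knockout minus wild type in replicates 1 and 2, between the bounds of 0.3 and 0.8 set beforehand. For replicate 3 minus replicates 1 and 2 the r was 0.803 in the wild type and 0.809 in the knockout, just past the upper bound, but counts of RNA do not measure DNA copies.

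With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. All 10 gave as many genes past edgeR's adjusted threshold as the real split, since each gave 0 (at an unadjusted p under 0.05 the real split had 2675 genes and the split of wild type replicates 1 and 2 with knockout replicate 3 had 3804; DESeq2 called 1056 in the real one). By the study's rule the real split gave 723 genes, reached by 1 split, the real one, and the highest other gave 718: wild type replicates 1 and 2 with knockout replicate 3, which is the real split with the replicate 3 labels exchanged. For lists, 6 splits reached the real count of 6, and the same other split gave the highest, 14. Among the 4 splits that part every numbered pair, the rule gave 723, 718, 4 and 8 genes, which points to a structure of the samples: the high counts came where replicates 1 and 2 of a genotype stayed together.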

How the results depend on the processing

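The settings that leave out replicate 3 of both genotypes, add it as a batch term, halve the counts or remove chromosome medians were chosen only after the result was seen, as were all settings of replicates 1 and 2. Of the values of single genes and lists under alternatives, 197 kept their direction and side of the threshold, 34 newly passed it, 21 no longer passed and 0 reversed. The edgeR count of 0 genes over all 6 libraries became 1056 with DESeq2, 9002 in replicates 1 and 2, and 0 to 2259 with 1 library left out, rising to 751 without wild type replicate 3 and 2259 without knockout replicate 3. Leaving out any of the other 4 libraries left it at 0. The edgeR dispersion was 0.018 in replicates 1 and 2 against 0.217 over all 6 libraries. Of the 1056 DESeq2 calls, 921 lay among the genes edgeR tested. Why DESeq2 called more was not tested. The study's rule gave 723 genes, and 1423 with DESeq2, 1494 with no count filter, 410 with 1 CPM required in 3 libraries, 2074 in replicates 1 and 2, and 528 to 1855 with 1 library left out (1550 without wild type replicate 3, 1855 without knockout replicate 3). Its excess of higher genes, 418 against 305, turned with limma-voom (353 and 371), the replicate block (227 and 285), replicate 3 as a batch term (381 and 396), and without knockout replicate 1 (265 and 306) or 2 (247 and 281). Of these the filters change how many genes are tested; otherwise the cause was not tested. Cmklr1 kept its direction, at -4.27 with DESeq2, -4.67 in replicates 1 and 2 and -3.82 to -4.50 with 1 library left out; the first 2, and those without a replicate 3 library, passed the adjusted threshold. Lists moved numbered 6, and 13 in replicates 1 and 2, 4 to 12 with 1 library left out (12 without knockout replicate 3, 4 without knockout replicate 1), 0 with camera and an estimated correlation, and 0 with fry. With the replicate block edgeR called 0 genes (smallest adjusted p 0.408; 2211 genes at an unadjusted p under 0.05), the rule gave 512, and apart from the cholesterol and pericyte lists no call of the report changed. On the 500 most variable genes the replicate 3 libraries correlated at 0.926 rather than 0.976. In replicates 1 and 2 the gene count ran from 6587 to 9413 and the list count from 10 to 14 with 1 library left out; the list count was 17 with fry and 0 with an estimated correlation. By fry in replicates 1 and 2, lists called by camera that did not pass were oxidative phosphorylation (adjusted p = 0.0548), oxidant genes (0.0944) and the unfolded protein response (0.101). At the spread of all 6 libraries, 2% of 2-fold changes were recovered in simulated genes that varied independently. Changes of that size were thus nearly all missed even there.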

Other observations

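The genes in the next 2 paragraphs were chosen after their values were seen, and no list of them was fixed or tested as a group; the test around Cmklr1 was fixed before its result.

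Some transcription factors of body regions and germ layers differed between the pairs of libraries. Of 23 tested Hox genes, which pattern the body axis, 15 rose and 3 fell in knockout replicates 1 and 2 (median log2 fold change 1.02); in replicate 3 the median ratio was 0.14, and the interaction passed for 13 in edgeR. Hoxc8 stood at 1.68 and 1.65 CPM in wild type replicates 1 and 2, 37.0 and 40.3 CPM in knockout replicates 1 and 2, and 4.1 and 2.28 CPM in replicate 3. Hoxb9 (log2 fold change 2.89 ± 0.23 SE) and Hoxa5 (2.07 ± 0.13) rose too. Nkx2-1, a factor of foregut and forebrain, stood at 19.6 and 21.7 CPM in wild type replicates 1 and 2 and at 0 counts in knockout replicates 1 and 2. The foregut and pharyngeal gene Pax9 fell (-5.13 ± 0.29), and so did the heart and gut endoderm factor Gata4 (-5.25 ± 0.22), which lay under 0.17 CPM in both replicate 3 libraries, and Foxc1 (-3.61 ± 0.14). The limb factor Tbx3 rose (6.12 ± 0.41), as did Gata2 (3.14 ± 0.16), at 105 and 98.2 CPM in replicate 3, and Twist1 (1.34 ± 0.13).

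Besides the imprinted Meg3 and Rian, Mirg (log2 fold change 7.16 ± 0.32 SE) and the paternally expressed Dlk1 of the same region rose in knockout replicates 1 and 2, Dlk1 from 1.27 and 0.843 CPM to 64.0 and 60.3 CPM, and H19 on another chromosome rose (7.58 ± 0.37). In replicate 3 these genes went apart, with log2 ratios of knockout over wild type of 1.51 for H19, 0.07 for Mirg, -0.79 for Dlk1 (190 CPM in the wild type and 110 CPM in the knockout), -1.35 for Meg3 and -1.60 for Rian.

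The hypothesis that DNA flanking the knockout allele changes the expression of neighboring genes was tested on 121 genes within 5 Mb of Cmklr1. Their median absolute log2 difference was 0.44 in replicates 1 and 2, at percentile 32.5 of 2287 windows elsewhere, and 0.303 in replicate 3, at percentile 58.1. These medians show no larger shift around Cmklr1 than elsewhere. A change in a few neighboring genes would hardly move such a median, so the test cannot decide the hypothesis.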
